A study of Sus scrofa with 9 samples.

How the data were processed

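Left ventricular tissue of wild type, untreated neonatal pigs was profiled by RNA sequencing at postnatal day 0, day 7 and day 15, with 3 libraries per age and 9 in all. Per the labels' protocols, the tissue was frozen in liquid nitrogen, RNA was extracted with a NucleoSpin RNA kit and libraries were made with the Illumina TruSeq stranded mRNA protocol. Libraries are named by age and by the replicate number in their titles (day 0: 4, 5 and 6; day 7: 2, 5 and 6; day 15: 1, 2 and 6).

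The authors deposited 1 table of length-normalised transcript abundances (TPM), with 22629 rows and 1 column per library, and all 9 columns were used. Each column has the same sum within rounding, as TPM values do. Trimmomatic 0.33, HISAT2 2.0.5 and kallisto 0.43.1 are named, per the submitters' processing notes, without their role or order. The genome build, the annotation and the use of strand in counting are not given in the sources used here. The table lists 15095 rows by gene symbol and 7534 by Ensembl pig gene identifier, of which 915 matched a reference table of gene names and 889 gave a symbol not already present. Values of 0 in every library were found in 4056 rows. TPM is a share of each library's total, so the depth behind a value is unknown, no counting interval is given, and a change in a very abundant transcript shifts all other values. Genes with near-identical copies, such as ribosomal protein and class I antigen genes, are less certain, since how shared reads were assigned is not given in the sources used here.

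Genes with a TPM of at least 1 in at least 3 libraries were tested (12268 genes). Values were taken to log2(TPM + 1), with a pseudocount of 1 TPM, and fold changes are on that scale, which understates the change of genes with low TPM. A linear model with 1 mean per age was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with a mean-variance trend, 6 residual degrees of freedom). The 3 contrasts (day 7 against day 0, day 15 against day 7, day 15 against day 0), an F test over the ages and the contrast of the first step minus the second step were each adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted p. A change of at least 2-fold means a log2 fold change of at least 1 in size. A single exact permutation of 3 against 3 libraries cannot give a two-sided p below 0.10, so gene-wise permutation tests were not used.

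Before the data were examined, 39 gene lists (cell division, contraction, metabolism, signalling, matrix, immune and stress responses, and markers of cell types that heart tissue can hold) were fixed, together with the tests, the alternatives and the rule for naming genes. A list was tested when at least 5 members passed the TPM filter (35 lists). For each list, the members past the gene-wise threshold were counted, over all genes tested and adjusted over the list alone, and limma's camera was run with a preset correlation of 0.01, adjusted over the lists and the 3 contrasts. Camera with an estimated correlation, camera on ranks and fry were alternatives. Lists share members, and heart muscle itself expresses some markers of other types.

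Named genes followed a fixed rule. For each contrast, the 6 largest rises and the 6 largest falls were taken among genes past the threshold with a symbol, a mean of at least 5 TPM in the higher age and no overlap between libraries. For each list and contrast, up to 4 members with the smallest adjusted p below the threshold and the most abundant member were taken. A set of genes fixed by name and, for the contrast of steps, 4 genes per direction were added. The text gives a part of the genes the rule named. Genes outside the rule appear in the closing section only, and were chosen after their values were seen. The exception is the group of other amino acid response members there, which was listed before its values were looked at.

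The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without mitochondrially encoded genes and the 20 most abundant genes, no trend, a robust fit, library weights, a fit on the 2 ages compared, the replicate number as a block, and leaving out each library in turn. TPM rescaled without the most abundant gene was added after the data were seen. Other splits of the libraries were counted, all 10 for 2 ages and 100 drawn at random for 3 ages.

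Simulated tables had the means and moderated spreads of the real genes with independent noise, and 200 genes of at least 5 TPM changed by known folds. The limma step was tested on these. For day 7 against day 0 (12067 genes in the step) it called 6.0% of the genes changed 1.5-fold, 61.2% of those changed 2-fold and 97.0% of those changed 4-fold, and 0.0590% of unchanged genes. For day 15 against day 7 (12106 genes) the shares were 3.0%, 64.2%, 100% and 0.0756%, and for day 15 against day 0 (12031 genes) 6.0%, 65.7%, 98.5% and 0.0338%. In these tables, changes under 2-fold were thus often missed at 3 libraries per age. The adjusted threshold depends on how many genes change and on how genes move together. The shares need not hold for the deposited table, where 2031 genes passed at day 7. No pair of libraries shared more than 21 identical values among the genes tested, and none was taken as a duplicate. Figures were drawn with matplotlib 3.10.9. No reads were analysed here.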

Results

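Gene expression in the left ventricle of the neonatal pig was measured by RNA sequencing at 3 postnatal ages. The libraries came from untreated wild type animals on postnatal day 0, day 7 and day 15, with 3 libraries per age. The values were length-normalised transcript abundances (TPM), which carry no record of sequencing depth, so the depth of each library is unknown here. Each library listed between 11290 and 12164 genes at 1 TPM or more. A single unnamed gene, ENSSSCG00000032277, took 24.0% (day 0, replicate 6) to 46.0% (day 15, replicate 1) of all TPM, and the mitochondrially encoded transcripts took 16.5% to 24.6%. The labels do not say that the libraries of an age came from separate animals, so the p-values measure the spread between these samples.

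Across the 12268 genes tested, Pearson correlations on log2(TPM + 1) were 0.965 to 0.991 within an age and 0.914 to 0.977 between ages (a description across genes, which are not independent replicates). The first principal component held 45.0% of the variance and separated the newborn libraries, at -44.4, -23.9 and -53.6, from the day 7 libraries at 11.5 to 17.6 and the day 15 libraries at 23.8 to 26.4. Newborn replicate 5 lay closest to the older libraries. The second component held 18.8% and spread the libraries within each age.

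**Figure D1:**
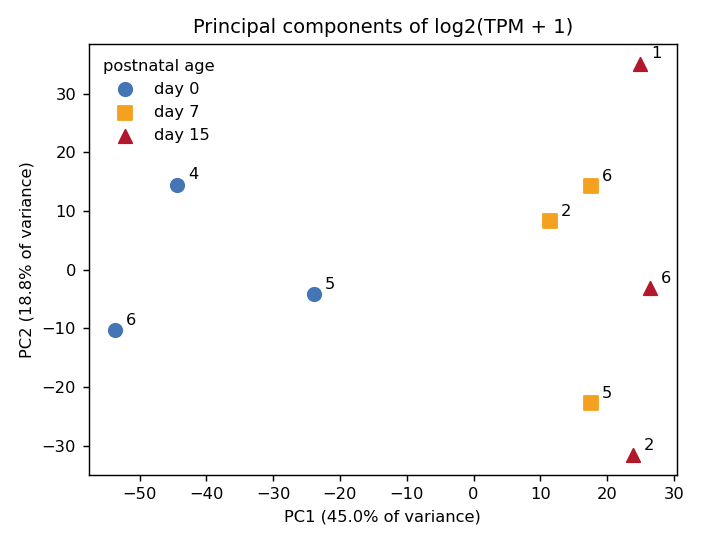
First and second principal components of log2(TPM + 1) over the 12268 tested genes, 1 point per library, numbered by replicate, with the share of variance on each axis. The newborn libraries lie between -53.6 and -23.9 on the first component, and all libraries of day 7 and day 15 lie above 11.

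The comparison of day 7 with day 0 asked what changed in the ventricle over the first week after birth. Many genes of cell division rose. Of 29 genes of DNA replication and the G1/S transition, 20 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.88. Of 26 genes of G2/M and mitosis, 16 rose and 0 fell (23 and 0 adjusted over the list alone), median 1.14, and of 21 cytokinesis genes, 12 rose and 0 fell (15 and 0 adjusted over the list alone), median 1.18. Thymidylate synthase, TYMS, went from 2.99 ± 2.81 to 22.5 ± 7.72 TPM (mean ± SD, n = 3 per age here and below), a log2 fold change of 2.72 ± 0.40 (SE) with a limma adjusted p of 0.00326. UHRF1, needed to maintain DNA methylation through replication, went from 2.25 ± 2.05 to 11.5 ± 3.65 TPM (2.08, limma adjusted p = 0.00540). The cyclin CCNE2 rose by 1.26, the spindle checkpoint kinase BUB1B by 1.75, the kinetochore protein CENPF by 1.40 and the cytokinesis genes CIT, KIF14 and IQGAP3 by 1.19, 1.34 and 1.60 on the log2(TPM + 1) scale. The most abundant member of the G2/M list, UBE2C, had 27.1 ± 24.8 TPM at day 0 and 47.9 ± 12.9 TPM at day 7, and its difference did not pass (limma adjusted p = 0.103). The newborn libraries differed here, since the median G2/M deviation from the 9-library mean was -0.99 in replicate 4, 0.27 in replicate 5 and -0.89 in replicate 6. The erythroid markers were also highest in replicate 5, at -0.46, 0.56 and -0.69 in replicates 4, 5 and 6 (0.44, 0.38 and -0.23 in day 7 replicates 2, 5 and 6). Without replicate 5, 25 of 26 G2/M genes rose, with a median of 1.58. The calls of TOP2A and KIF4A were lost without newborn replicate 4 or 6, and that of PCNA in 10 of 22 settings. Those of TYMS and UHRF1 were kept in all 22 settings. Those of CCNE2, BUB1B, CENPF, CIT, KIF14 and IQGAP3 were kept in each of the 21 settings in which they were tested.

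Among 17 cell cycle inhibitors, 3 rose and 2 fell (3 and 3 adjusted over the list alone). GADD45A fell from 28.1 ± 3.38 to 8.61 ± 1.22 TPM (-1.60, limma adjusted p = 7.90e-04), while CDKN2C (1.46) and CCNG2 (1.27) rose. The calls of CDKN2C and CCNG2 were lost in 5 and 3 of the alternative settings. CDKN1A, the p21 inhibitor, fell from 37.5 ± 7.62 to 17.6 ± 7.50 TPM (-1.13, limma adjusted p = 0.0353, lost in 4 settings).

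The largest falls at day 7 included genes of the cell stress response. TRIB3, a pseudokinase induced by endoplasmic reticulum and amino acid stress, fell from 45.2 ± 12.9 to 2.02 ± 0.717 TPM (-3.92 ± 0.30 SE, limma adjusted p = 7.37e-05). DDIT3, which encodes the stress transcription factor CHOP, fell from 68.5 ± 26.5 to 5.57 ± 1.61 TPM (-3.35, limma adjusted p = 2.91e-04). IFRD1 fell by -3.04, and the sodium-proton exchanger SLC9A3 by -3.05. CMTM5 (138 ± 24.7 to 16.6 ± 20.4 TPM, -3.66) and IL25 (111 ± 10.9 to 14.2 ± 17.3 TPM, -3.55) fell too, with limma adjusted p = 0.0103 and 0.0112. CMTM5 and IL25 are neighbours in the RefSeq annotation of Sscrofa11.1 and their ratio ranged 1.44-fold over the 9 libraries while IL25 ranged 79.3-fold. Their calls were lost without newborn replicate 6 (limma adjusted p = 0.0563 and 0.0585) and with a robust fit. The call of SLC9A3 was also lost without newborn replicate 6 (limma adjusted p = 0.0535).

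Most genes of fuel use did not pass the threshold over the first week, nor did most genes tested (2031 of 12268 passed). Of 30 genes of fatty acid uptake and oxidation, 1 rose and 7 fell (3 and 9 adjusted over the list alone). These included the lipid droplet proteins PLIN5 (36.3 ± 12 to 8.26 ± 3.47 TPM, -2.01) and PLIN2 (-1.45), the mitochondrial carrier UCP3 (-2.54) and the heart fatty acid binding protein FABP3, which fell from 679 ± 227 to 222 ± 74.6 TPM (-1.59, limma adjusted p = 0.00632). CPT1A, the liver-type carnitine palmitoyltransferase, fell by -1.11, while the muscle type CPT1B had 317 ± 74.7 TPM at day 0 and 320.3 ± 49.7 TPM at day 7 (limma adjusted p = 0.935). After median-of-ratios scaling, 6 of the fatty acid genes rose and 9 fell. Of 23 glycolysis genes, 0 rose and 4 fell (0 and 6 adjusted over the list alone). The enolase ENO1 fell from 279 ± 54.6 to 123 ± 21.8 TPM (-1.17) and the lactate transporter SLC16A3 from 42.7 ± 7.68 to 9.55 ± 4.10 TPM (-2.11), whereas the most abundant member, GAPDH, had 6499 ± 319.9 and 4842 ± 1059 TPM (limma adjusted p = 0.112). In the TCA cycle list 0 rose and 5 fell of 24 (0 and 6 adjusted over the list alone), and in the nuclear-encoded respiratory chain list 0 rose and 5 fell of 39 (0 and 4 adjusted over the list alone), with cytochrome c, CYCS, at 938 ± 166 and then 421 ± 56.8 TPM (-1.15, limma adjusted p = 0.00462). Among 19 genes of ketone and branched-chain amino acid breakdown, 3 rose and 3 fell (4 and 3 adjusted over the list alone), with the ketone body enzyme BDH1 rising from 3.58 ± 1.12 to 13.7 ± 5.13 TPM (1.66) and the branched-chain dehydrogenase subunit BCKDHB falling by -1.08.

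Contractile genes moved in both directions. Of 21 mature sarcomere genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone). The M-band protein MYOM2 rose from 35.4 ± 7.39 to 146 ± 61.6 TPM (1.96, limma adjusted p = 0.00325), and cardiac alpha actin, ACTC1, fell from 13981 ± 1878 to 6279 ± 1797 TPM (-1.19, limma adjusted p = 0.0129, lost without newborn replicate 6 at 0.0712). Triadin, TRDN, a protein of the calcium release complex, rose by 1.26. In the fetal and neonatal contractile list 0 rose and 3 fell of 14 (0 and 5 adjusted over the list alone), among them TAGLN (-0.87) and TPM2 (-0.76), whose calls were lost in 2 and 10 of 22 settings, and after median-of-ratios scaling 1 fell. Skeletal actin, ACTA1, had 3261 ± 2420.5 and 5271 ± 2919 TPM, MYH7 8766 ± 1535 and 7819.6 ± 1172 TPM, and the slow skeletal troponin TNNI1 1003 ± 52.5 and 908 ± 106 TPM, and none of these 3 passed.

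Of 35 matrix genes, 8 rose and 0 fell (12 and 0 adjusted over the list alone), and 27 did not pass over all genes. The basement membrane proteoglycan AGRN went from 10.4 ± 2.98 to 42.7 ± 19.6 TPM (1.88, limma adjusted p = 0.00462) and fibrillin, FBN1, from 15.9 ± 4.09 to 46.5 ± 6.36 TPM (1.5). Of 13 antigen presentation genes, 7 rose and 0 fell (11 and 0 adjusted over the list alone), and of 25 interferon-stimulated genes, 1 rose and 0 fell, although their median was 1.20. The antigen presentation level of day 7 replicate 5 lay 0.85 above the 9-library mean, against -0.16 and -0.07 in replicates 2 and 6, and without replicate 5 each of the 7 calls was lost, with a median of 0.82 in place of 1.18. The interferon level of day 7 replicate 5 lay 1.32 above the 9-library mean, against -0.96 and -0.80 in replicates 2 and 6, and without replicate 5 the median was 0.47. LGALS3BP (2.94), GNLY, a granule protein of cytotoxic lymphocytes (2.36), and BST2, an antiviral membrane protein (2.12), were among the 6 largest rises, together with THY1 (2.17), TYMS and UHRF1. The calls of LGALS3BP, GNLY and BST2 were lost in 4, 8 and 5 settings, including the fits without newborn replicate 4 (limma adjusted p = 0.0714, 0.0851 and 0.0874) and newborn replicate 6 (limma adjusted p = 0.0802, 0.113 and 0.108). Of 37 ribosomal protein genes, 0 rose and 6 fell (0 and 7 adjusted over the list alone), and of 19 immediate early and heat shock genes 0 rose and 6 fell (0 and 7 adjusted over the list alone), including MYC, which fell from 27.1 ± 7.89 to 10.4 ± 1.95 TPM (-1.27, limma adjusted p = 0.00929, lost without newborn replicate 6).

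In smaller groups, the growth factor list (NRG1, FGF and insulin signalling) had 1 rose and 6 fell of 22, with FGFR2 and FGF1 falling by -1.44 and -1.10 and IGFBP7 rising by 1.17. Cardiac transcription factors had 0 rose and 2 fell of 17 (SRF -1.20, GATA4 -0.72). In the circadian clock list 1 rose and 4 fell of 18, with CIART up by 1.30 and ARNTL and NR1D1 down by -0.96 and -1.08. Glucocorticoid-responsive genes had 0 rose and 2 fell of 14 (DDIT4 -1.38), mitochondrial biogenesis regulators 0 rose and 2 fell of 17 (ESRRA -1.10), fetal growth and imprinted genes 0 rose and 1 fell of 14 (HMGA1 -0.88), hypoxia-inducible factor targets 0 rose and 1 fell of 20 (VEGFA -1.30), calcium handling and ion channel genes 1 rose and 1 fell of 30, and the Hippo and mitochondrially encoded lists had 0 of 18 and 0 of 13 past the threshold. The calls of GATA4 and VEGFA were lost in 4 settings each, those of SRF and HMGA1 in 3, that of ESRRA in 2 and that of NR1D1 in 1, each of them without newborn replicate 6.

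Markers of other cell types are given beside the 2031 of 12268 genes that passed at day 7. Of 13 endothelial markers, 2 rose and 2 fell, with CDH5 (0.94) and PECAM1 (0.67) up and FABP4 (-1.76) and EMCN down. Of 13 fibroblast markers 2 rose and 0 fell (PI16 1.88, COL3A1 0.76), of 12 pericyte and smooth muscle markers 2 rose and 0 fell (ABCC9 0.94), of 13 macrophage markers 1 rose and 0 fell (CSF1R 0.79), of 5 erythroid markers 1 rose and 0 fell (GYPC 0.96), of 10 cardiomyocyte markers 1 rose and 0 fell (CKM 0.84) and of 6 adipocyte markers 0 rose and 1 fell (FABP4). Of up to 22 settings, the calls were lost in 10 for CSF1R, 9 for COL3A1, 7 for EMCN, 6 for GYPC and 5 for PECAM1. They were lost in 4 for CKM, 2 for PI16 and 1 for CDH5, and in none for FABP4 and ABCC9. Atrial and epicardial markers had 0 of 8 and 0 of 5 past the threshold. Hemoglobin beta, HBB, had 702 ± 459 TPM at day 0, where the 3 libraries held 504, 1227 and 374 TPM, and 834 ± 321 TPM at day 7.

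In all, 2031 of 12268 genes changed at day 7 (limma, adjusted p under 0.05), of which 941 rose and 1090 fell, and 643 changed at least 2-fold, 335 up and 308 down. The libraries of the 2 ages did not overlap for 41.4% of genes, where chance gives 10%. After median-of-ratios scaling 3827 genes changed and the share that rose was 53.9% in place of 46.3%, and it was 64.0% of 3679 genes when mitochondrial transcripts and the 20 most abundant genes were left out of the total. Of the genes changed at least 2-fold, 52.1% rose on the deposited TPM and 66.1% after median-of-ratios scaling. The count was 556 without newborn replicate 4, 372 without newborn replicate 6 and 2446 without newborn replicate 5. It was 1120, 1252 and 861 without day 7 replicates 2, 5 and 6. A fit with 1 library fewer detects less, and without newborn replicate 4 or 6 the deviating replicate 5 weighs more in the newborn mean. The lower counts thus do not show which libraries the calls rest on. The share that rose was 58.8% without day 7 replicate 6 and 37.9% without newborn replicate 4. Among genes changed at least 2-fold these shares were 63.1% and 35.8%, so the direction was not stable. The camera test called 13 of the 35 lists, 6 up (the 3 cell division lists, extracellular matrix, interferon-stimulated genes and antigen presentation) and 7 down. Each of these calls was lost with an estimated correlation (adjusted p = 0.944 with an estimated correlation for each list).

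**Figure D2:**
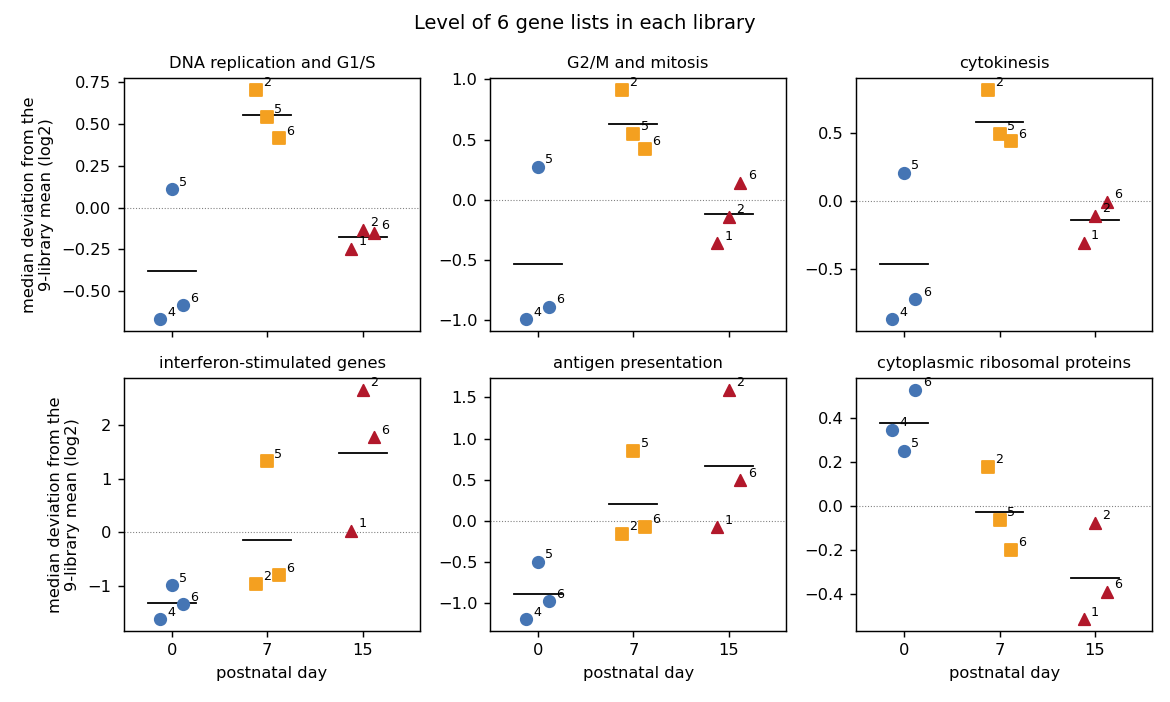
Level of 6 gene lists in each library, as the median over list members of the deviation from the 9-library mean on log2(TPM + 1), against postnatal day; points are libraries numbered by replicate and lines are the means of 3. G2/M genes lay at -0.99 and -0.89 in newborn replicates 4 and 6, at 0.27 in newborn replicate 5 and at 0.42 to 0.91 at day 7, and interferon-stimulated genes at -1.62 to -0.99 in newborns and 0.03 to 2.65 at day 15.

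The comparison of day 15 with day 7 asked what changed over the second week. Few single genes passed, and 21 did so, 5 up and 16 down, all of them by at least 2-fold (limma, adjusted p under 0.05). The direction was not stable, since without day 7 replicate 5 there were 59, 36 up and 23 down. The monocarboxylate transporter SLC16A3 rose, from 9.55 ± 4.10 to 27.1 ± 4.09 TPM (1.47 ± 0.26 SE, limma adjusted p = 0.0497). The retinoid receptor RXRG rose from 3.97 ± 1.98 to 12.6 ± 3.07 TPM (1.49) and the growth factor FGF9 from 1.16 ± 0.253 to 4.06 ± 0.382 TPM (1.23, limma adjusted p = 0.0346). The angiogenesis regulator VASH1 fell from 14.4 ± 3.40 to 4.09 ± 1.48 TPM (-1.62), the T-box factor TBX4 from 6.88 ± 3.58 to 0.684 ± 0.273 TPM (-2.12), and FBF1, CRADD, ST6GAL1 and STX6 fell by -1.47, -1.23, -1.10 and -1.08. The call of each of these 9 genes was lost in 7 to 16 of up to 22 alternative settings, and without day 7 replicate 2, day 7 replicate 6 or day 15 replicate 6 no gene in the whole table passed.

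Between day 7 and day 15, 0 members of the cell division lists passed the threshold over all genes. Their median log2 fold changes were -0.67 for DNA replication (0 and 19 adjusted over the list alone), -0.76 for G2/M (0 and 0 adjusted over the list alone) and -0.75 for cytokinesis (0 and 5 adjusted over the list alone). These medians were negative under each scaling tried. As examples, BUB1B had 8.53 ± 0.697 TPM at day 7 and 4.11 ± 1.03 TPM at day 15 (limma adjusted p = 0.273), and PCNA, the most abundant member of the replication list, 44.4 ± 5.46 and 23.3 ± 4.65 TPM (limma adjusted p = 0.102). The interferon-stimulated genes had the largest positive median of the 35 lists, 1.54, with 0 of 25 past the threshold. Its most abundant member, IFI6, was spread widely at 99 ± 127 and 559 ± 524 TPM (limma adjusted p = 0.223).

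Glycolysis genes had a median of 0.26 (1 rose and 0 fell, 3 and 0 adjusted over the list alone) and matrix genes -0.44 (0 past the threshold, 0 and 1 adjusted over the list alone). The camera test with the preset correlation called 16 lists at day 15 against day 7, 10 up and 6 down, and none of these calls held with an estimated correlation (adjusted p = 0.944 with an estimated correlation for each) or with fry. Those down were the 3 cell division lists, extracellular matrix, ribosomal proteins (-0.30) and pericyte and smooth muscle markers (-0.42). Those up were interferon-stimulated genes, antigen presentation (0.38), glycolysis, the TCA cycle (0.10), the respiratory chain (0.03), ketone and branched-chain breakdown (0.13), hypoxia-inducible factor targets (0.17), macrophage markers (0.19), cardiomyocyte markers (0.01) and fatty acid genes. The fatty acid list was called up although its median was -0.03 and its mean -0.03, where the median of all genes was -0.15, and its median was positive under each other scaling. At an unadjusted p under 0.05, 1565 genes differed between day 15 and day 7, where chance gives 613.4, and 19.4% of genes had no overlap between the libraries of the 2 ages, where chance gives 10%. Median-of-ratios scaling gave 11 genes, 36.4% of them up in place of 23.8%, and a fit with library weights gave 3095.

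The comparison of day 15 with day 0 spanned both weeks. Genes of the interferon response were the group that rose most. Of 25 interferon-stimulated genes, 21 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 2.74. The antiviral GTPase MX1 went from 1.93 ± 1.10 to 122 ± 83.6 TPM (5.12 ± 0.87 SE, limma adjusted p = 0.00338), IFI6 from 14.5 ± 9.57 to 559 ± 524 TPM (4.87), RSAD2 from 1.22 ± 0.878 to 81.7 ± 60.1 TPM (4.81) and the ubiquitin-like ISG15 from 3.43 ± 1.51 to 114 ± 92.3 TPM (4.25). LGALS3BP and ISG12(A) completed the 6 largest rises, at 4.79 and 4.43. The 3 day 15 libraries differed widely in this group, with MX1 at 33.5, 199 and 134 TPM, and every one lay above the newborn libraries, at 1.64, 1.01 and 3.15 TPM. Of 13 antigen presentation genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone). B2M, the light chain of class I molecules, went from 114 ± 14.4 to 636 ± 493 TPM (2.19, limma adjusted p = 0.00723), the peptide transporter TAP1 from 4.64 ± 1.31 to 40.1 ± 31.4 TPM (2.57) and the invariant chain CD74 from 118 ± 29.4 to 353 ± 152 TPM (1.52).

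Macrophage markers moved less, with 2 rose and 0 fell of 13 (0 and 0 adjusted over the list alone), a median of 0.36 and the most abundant, C1QA, at 16.2 ± 3.21 and 50.1 ± 42.6 TPM (limma adjusted p = 0.0610). The 2 that rose, CSF1R (0.80) and C1QC (1.35), lost their calls in 8 and 6 settings. The lymphocyte list had 3 members above the TPM filter and none passed.

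Ribosomal protein genes fell. Of 37 tested, 0 rose and 31 fell (0 and 35 adjusted over the list alone), with a median of -0.72 against -0.19 for all genes. RPL3 fell from 139.8 ± 16.9 to 45.7 ± 7.09 TPM (-1.59, limma adjusted p = 0.00115) and RPS18 from 1121 ± 70.9 to 559.6 ± 73.5 TPM (-1.01). After median-of-ratios scaling 21 fell and 0 rose. The reads of ribosomal protein genes can be shared with processed copies, and how the authors' counting treated these is not given in the sources used here. Immediate early and heat shock genes had 0 rose and 6 fell of 19, with MYC at 6.37 ± 1.98 TPM (-1.92).

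Of 17 cardiac transcription factors, 0 rose and 7 fell at day 15 against day 0 (0 and 7 adjusted over the list alone), including GATA4, from 69.4 ± 9.62 to 36.5 ± 5.95 TPM (-0.91, limma adjusted p = 0.00608), GATA6 (-0.98), SRF (-1.25) and MYOCD (-1.05), the last 3 lost in 1, 2 and 2 settings. After median-of-ratios scaling 1 rose and 5 fell. In the fetal and neonatal contractile list 1 rose and 6 fell of 14 (2 and 8 adjusted over the list alone). Among these, the smooth muscle genes CNN1 (133 ± 50.6 to 28.1 ± 6.68 TPM, -2.15), TAGLN (-1.18) and ACTA2 (-1.01) fell, and MYH11 of the pericyte and smooth muscle list fell by -1.42. The slow skeletal troponin TNNT1 rose from 49.2 ± 5.23 to 300.4 ± 105 TPM (2.53, limma adjusted p = 0.0124, lost without newborn replicate 6 at 0.0519). Of the mature sarcomere genes 4 rose and 2 fell of 21 (4 and 2 adjusted over the list alone), with ACTC1 falling to 4367 ± 1311 TPM (-1.72) and MYOM2 rising to 92.8 ± 25.2 TPM (1.35). Muscle creatine kinase, CKM, rose from 177 ± 8.99 to 488 ± 104 TPM (1.44). The natriuretic peptide gene NPPA fell by -3.96, from 977 ± 964 to 89.0 ± 100.1 TPM (limma adjusted p = 0.0393), and its call was lost in 12 settings, among them the fits without newborn replicate 4, 5 or 6 (limma adjusted p = 0.0544, 0.0958 and 0.0998) and day 15 replicate 1 or 6 (limma adjusted p = 0.141 and 0.0677). NPPB had 114 ± 97.4 and 27.5 ± 40.5 TPM and did not pass.

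Metabolic genes were mixed by day 15. Among fatty acid genes 4 rose and 10 fell of 30 (5 and 12 adjusted over the list alone), with CPT1A down from 47.9 ± 10.8 to 15.5 ± 1.43 TPM (-1.54), PLIN5 -2.24 and PDK4 -1.77 (lost in 4 settings), and after median-of-ratios scaling 7 rose and 9 fell. In glycolysis 1 rose and 3 fell of 23, in the TCA cycle 0 rose and 3 fell of 24 and in the respiratory chain 0 rose and 5 fell of 39. After median-of-ratios scaling the medians of these 3 lists turned from -0.07, -0.20 and -0.17 to 0.20, 0.07 and 0.10, so their direction depends on the scaling. BDH1 rose from 3.58 ± 1.12 to 15.1 ± 2.13 TPM (1.83) and BNIP3, a hypoxia-induced gene of mitochondrial turnover, from 85.0 ± 10.6 to 203 ± 28.1 TPM (1.25). AGRN reached 67.1 ± 15.9 TPM (2.58) and the fibroblast gene PI16 rose from 7.45 ± 3.32 to 49.2 ± 13.3 TPM (2.61).

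Few cell division genes differed from their newborn level at day 15. Of 26 G2/M genes 0 passed, with a median of 0.45. In DNA replication 2 rose and 2 fell of 29, with TYMS at 12 ± 2.56 TPM (1.90) and CDK4 falling from 16.6 ± 1.34 to 8.38 ± 0.969 TPM (-0.91), and in cytokinesis 1 rose and 1 fell of 21. Newborn replicate 5 set part of these medians, and without it that of G2/M was 0.81. TRIB3 stayed low at 1.05 ± 0.797 TPM (-4.54, limma adjusted p = 2.05e-05), as did IFRD1 (-2.99), CMTM5 (-3.91) and IL25 (-3.88), and TCTEX1D1 fell from 15.3 ± 3.30 to 0.911 ± 1.25 TPM (-3.26).

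**Figure D3:**
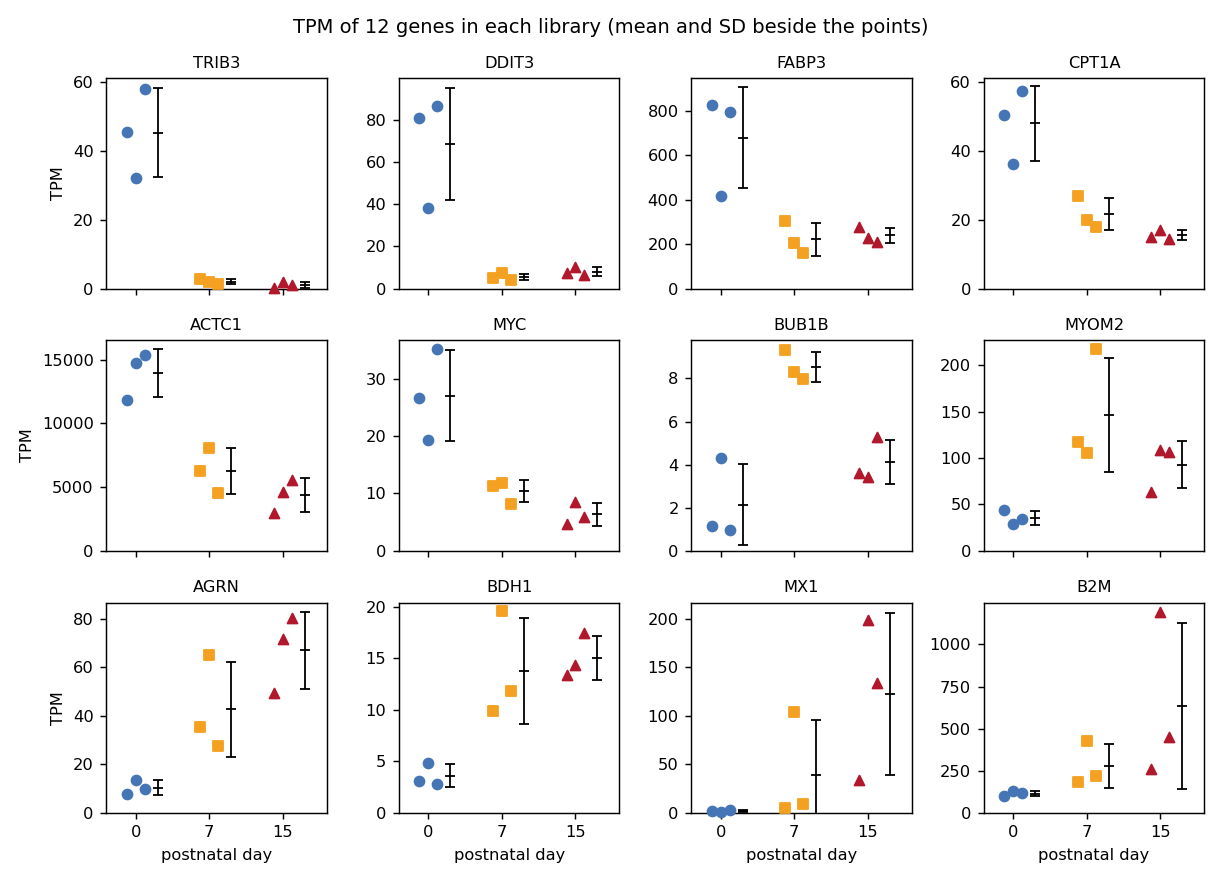
TPM of 12 genes in each library on linear axes that start at 0, against postnatal day, with the mean and SD of 3 libraries beside the points; parts of an SD below 0 are not drawn. TRIB3 fell from 45.2 ± 12.9 to 2.02 ± 0.717 TPM by day 7, and MX1 was high in day 7 replicate 5 (104 TPM) and in day 15 replicates 2 and 6.

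The rest of the lists at day 15 against day 0 are given beside 2933 of 12268 genes called in all, 678 up and 2255 down. For calcium handling and ion channels 2 rose and 4 fell of 30 (TRDN 1.34, S100A1 1.23), for growth factor signalling 3 rose and 7 fell of 22 (IGFBP7 1.11, IGFBP3 -1.30), for mitochondrial biogenesis 0 rose and 5 fell of 17, and for cell cycle inhibitors 2 rose and 3 fell of 17 (GADD45A -1.66). For ketone and branched-chain breakdown 3 rose and 2 fell of 19, for hypoxia targets 3 rose and 1 fell of 20, for matrix genes 2 rose and 0 fell of 35 and for Hippo genes 0 rose and 3 fell of 18. For glucocorticoid-responsive genes 0 rose and 3 fell of 14, for clock genes 1 rose and 3 fell of 18 (NR1D1 -1.19) and for fetal growth genes 0 rose and 2 fell of 14. Among marker lists, endothelial genes had 0 rose and 2 fell of 13, fibroblast genes 1 rose and 0 fell of 13, pericyte and smooth muscle genes 1 rose and 4 fell of 12, cardiomyocyte genes 1 rose and 1 fell of 10, erythroid genes 1 rose and 0 fell of 5 and atrial genes 0 rose and 2 fell of 8. Epicardial, adipocyte and mitochondrially encoded genes had 0 past the threshold. The neutrophil, Schwann cell and skeletal muscle lists had under 5 members above the filter and were not tested as lists. In these, S100A8 (-1.51) fell and CKM rose.

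In all, 2933 genes changed between day 0 and day 15 (limma, adjusted p under 0.05), 678 up and 2255 down, and 852 changed at least 2-fold, 313 up and 539 down. The excess of falls depended on the scaling, since the share that rose was 23.1% on the deposited TPM, 53.0% of 3829 genes after median-of-ratios scaling, 43.3% after quantile normalization and 36.7% when the most abundant gene was left out of the total. Of the genes changed at least 2-fold, 36.7% rose on the deposited TPM and 68.3% after median-of-ratios scaling. The median log2 fold change of all genes was -0.19 on the deposited TPM and 0.03 after median-of-ratios scaling. The count was 1794 without newborn replicate 4, 786 without newborn replicate 6 and 1375 without day 15 replicate 6. The share that rose also depended on single libraries, at 39.0% without day 15 replicate 1 and 13.5% without day 15 replicate 2. Among genes changed at least 2-fold these shares were 53.2% and 21.0%. The camera test called 10 lists, of which ribosomal proteins were down and interferon-stimulated genes, antigen presentation, the 3 cell division lists, matrix, ketone and branched-chain breakdown, hypoxia targets and macrophage markers up. None held with an estimated correlation (adjusted p = 0.944 with an estimated correlation for each).

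The changes at day 7 and at day 15 against the same newborn libraries overlapped. Of the genes that rose, 355 did so at both ages, where independent lists would share 52.0, and of those that fell 976, where independent lists would share 200.4. Groups simulated with no effect, with all 9 libraries redrawn as independent noise, shared 0.06 genes on average. Almost no gene is called without an effect, so this overlap cannot show how much comes from the shared newborn libraries. The fold changes correlated at 0.829 across genes, against 0.50 in the simulation, and their covariance was 0.271 against 0.0288. Part of the excess over independent lists may come from the shared newborn libraries, which were too few to be split.

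Over the 3 ages together 2705 genes changed by the limma F test (adjusted p under 0.05), with 415 without newborn replicate 6, 1014 without newborn replicate 4 and 1487 without day 15 replicate 6. A direct test of the first step (day 0 to day 7) minus the second step (day 7 to day 15) passed for 236 genes, with a positive difference in 188 (79.7%), a share that was 56.7% of 570 genes after median-of-ratios scaling. VASH1 rose in the first week (2.04) and fell in the second (-1.62), and the apelin gene APLN had 37.3 ± 3.50, 155 ± 78.3 and 57.8 ± 2.40 TPM at the 3 ages, with a step difference of 3.21 (limma adjusted p = 0.0151). SLC16A3 went the other way (-3.58), as did FABP4, at 257 ± 41.3, 78.7 ± 32.8 and 168 ± 12.1 TPM (-2.91). The count was 717 without newborn replicate 5, 14 and 16 without newborn replicates 4 and 6, 3, 64 and 0 without day 7 replicates 2, 5 and 6, and 88 without day 15 replicate 6 (2201 genes had an unadjusted p under 0.05 with all libraries).

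Of the genes fixed by name in advance, MKI67, MYH6, IGF2, HMGA2 and MYL7 were not matched to a row, and LIN28B and MEIS1 fell under the TPM filter. CDK1 had 10.5 ± 10.7, 22.4 ± 3.50 and 16.4 ± 5.61 TPM at the 3 ages and CCNB1 5.88 ± 5.00, 9.43 ± 2.21 and 5.72 ± 1.48 TPM, and neither passed in any comparison (the smallest limma adjusted p was 0.0662, for CDK1 at day 7). CCND2, CDKN1C, IGF2BP3, HK1, TNNI3, COL1A1 and MYL4 did not pass in any comparison either, with log2 fold changes at day 15 against day 0 of -0.14, 0.06, 0.11, 0.12, -0.22, 0.03 and -0.57.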

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

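These results stood out because the same gene changed by a different amount in the first week (day 0 to day 7) and in the second (day 7 to day 15), by a limma test of that difference that was fixed before the data were examined. In all, 236 genes passed. The 4 positive differences with the smallest adjusted p were those of the angiogenesis regulator VASH1, whose first step exceeded its second by 3.66 on the log2(TPM + 1) scale (limma adjusted p = 0.00696), the apelin gene APLN at 3.21 (limma adjusted p = 0.0151), CRADD at 2.29 and the transporter SLCO2B1 at 2.10. Each of these was higher at day 7 than at either other age in its mean TPM. The 4 negative differences named were DDIT3 at -3.83 and CHAC1 at -2.39, 2 genes of the amino acid and endoplasmic reticulum stress response that were low from day 7 on, and SLC16A3 at -3.58 and FABP4 at -2.91, which were lowest at day 7. SLC16A3 encodes a lactate transporter and FABP4 a fatty acid binding protein of capillary endothelium and fat cells. All 8 calls were lost without 1 or more single libraries (day 7 replicate 6 for each of the 8, day 7 replicate 2 for 7 of them).

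Of 100 drawn splits of the 9 libraries into 3 groups of 3, the real one included, 3 gave 236 genes or more. The highest of the others gave 2755. That split placed the 3 newborn libraries in the middle position, so the many genes it called point to the structure of the samples, in which the newborn libraries stand apart from all later ones. Each grouping was drawn in 1 order of its groups only, while the step test depends on which group is in the middle. Other orders of the real grouping were thus left out in advance, and 3 in 100 cannot be read as a chance share. For the F test over the 3 ages, 1 of 100 splits, the real one, gave 2705 genes, and the highest of the others gave 1498, also with the newborn libraries kept together.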

How the results depend on the processing

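The scaling without the most abundant gene alone was chosen after seeing the data; the other settings were fixed before. No named gene and no list reversed its call under any setting run. Over the named genes, 7102 values kept their side of the threshold, 839 lost and 113 gained a call, and over lists 2396 kept it, 159 lost and 58 gained. The counts changed much with the library left out. Leaving out each in turn gave 372 to 2685 genes for day 7 against day 0 (277 to 1055 at least 2-fold). It gave 0 to 59 for day 15 against day 7 (0 to 59 at least 2-fold) and 786 to 3275 for day 15 against day 0 (444 to 1202 at least 2-fold). The F test over the 3 ages gave 415 to 3191 and the 2 steps 0 to 717. Lists called were 12 to 16, 14 to 18 and 5 to 12 in the 3 comparisons. TPM holds no depth, so what depth limits could not be assessed. The cause was not tested for any of the shifts below.

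With a pseudocount of 0.1, 1034 genes changed at least 2-fold at day 7, 5 at day 15 against day 7 (5 at least 2-fold) and 141 differed between steps; with a pseudocount of 5 the counts at least 2-fold were 206, 6 and, for day 15 against day 0, 340. Without a filter, 1296 genes changed at day 7, 12 at day 15 against day 7 (4 at least 2-fold) and 44 between steps, and with a mean of at least 5 TPM, 1 (1 at least 2-fold) at day 15 against day 7 and 89 between steps. Median-of-ratios scaling gave 3827 genes at day 7, 11 at day 15 against day 7 (6 at least 2-fold), 4069 over the 3 ages and 570 between steps. Quantile normalization gave 3562, 10 (5 at least 2-fold) and 553 between steps. Without mitochondrial and the 20 most abundant genes there were 3679 (1121 at least 2-fold), 9 (9 at least 2-fold) and 644, and without the most abundant gene 3437 at day 7 and 484 between steps. Library weights gave 3490, 3095 (293 at least 2-fold) and 6410 genes in the 3 comparisons, 7435 over the ages and 1619 between steps, after a weight estimation that did not converge. A fit on only the 2 ages gave 2 (2 at least 2-fold) at day 15 against day 7. With an estimated correlation 0, 0 and 0 lists were called, and with fry 0, 0 and 0, against 13, 16 and 10.

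The replicate block (the replicate number as a factor) gave 857 genes at day 7, 126 at day 15 against day 7 (126 at least 2-fold; 91 up and 35 down, against 5 and 16 in the main fit), 919 at day 15 against day 0, 807 over the ages and 28 between steps. The libraries share only a number: same-numbered libraries correlated between -0.21 and 0.17 in their deviations from the age means, and the labels do not tie the numbers. Of the 7 libraries with a same-numbered library at another age, 3 correlated best with their own number, all of them numbered 6. The highest correlations between ages joined unlike numbers. They were 0.37 for day 7 replicate 2 with day 15 replicate 1 and 0.31 for day 7 replicate 5 with day 15 replicate 2. A link between same-numbered libraries is thus not shown by these values.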

Other observations

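The tests on newborn replicate 5, on the interferon genes and on CMTM5 and IL25 were chosen only after the results were seen, as were the leading genes of the amino acid stress group; the test of the other members of that group and the counts of other splits were written before their results were seen. A group outside the fixed lists stood out among the falls at day 7. ATF4, the transcription factor of the integrated stress response, fell from 427 ± 61.6 to 109 ± 16.9 TPM (mean ± SD, n = 3; log2 fold change -1.97, limma adjusted p = 3.58e-04), and its targets TRIB3, DDIT3, ATF5 (71.0 ± 17.2 to 10.9 ± 3.36 TPM), CHAC1 (5.09 ± 0.984 to 0.142 ± 0.0314 TPM) and the hormone FGF21 (4.62 ± 1.43 to 0.393 ± 0.207 TPM) fell with it, as did the amino acid transporters SLC3A2, SLC7A5 and SLC1A4 (-1.96, -1.95 and -2.56) and IFRD1 (-3.04). All 10 of these leading genes, chosen after their values were seen, were low at day 7 and at day 15, with medians of -2.48 and -2.77.

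A hypothesis is that these 10 belong to a wider fall of the amino acid response after birth, and it was tested on 26 other known members (tRNA synthetases, serine and asparagine synthesis, transporters) listed before their values were looked at. Of these, 17 fell and 1 rose at day 7, with a median of -0.907 (camera, preset correlation, Down, p = 7.57e-11; p = 0.0560 with an estimated correlation), and 23 fell and 1 rose at day 15 (median -1.13; p = 0.0624 with an estimated correlation). Asparagine synthetase, ASNS, fell from 23.1 ± 4.32 to 6.82 ± 2.27 TPM (-1.65) and alanyl-tRNA synthetase AARS1 from 107 ± 27.2 to 36.3 ± 5.65 TPM (-1.51). SESN2 fell from 2.66 ± 0.803 to 0.333 ± 0.0317 TPM (-1.44), while the folate enzyme ALDH1L2 rose by 0.82. The serine and folate genes PSAT1 (-0.54), PHGDH (-0.47), SHMT2 (-0.47), MTHFD2 (-0.20) and PSPH (0.51) were among the 8 that did not pass at day 7. The day 7 fall thus did not reach this part of the group, in which PSAT1, PHGDH, SHMT2 and MTHFD2 passed as falls at day 15. After median-of-ratios scaling 19 of the 26 fell at day 7. The fall is consistent with a stress response that was high at birth and over by day 7, but a response to collection of the newborn tissue was not tested.

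Newborn replicate 5 stood apart from replicates 4 and 6, also in erythroid markers (median deviation 0.56 against -0.46 and -0.69). Over 1055 genes changed at least 2-fold at day 7 in the fit without it, its median position was taken between the other newborns (0) and the day 7 mean (1). It was 0.456 (95% bootstrap interval over genes 0.435 to 0.483), below the position nearer 1 that a day 7 library with a newborn label would take. The genes were chosen on the same libraries that set positions 0 and 1, which draws any other library inward. How far was not measured, and the interval does not cover it. A mixture of newborn and day 7 RNA would place rising and falling genes alike in linear TPM, and these medians differed by -0.0244 with overlapping intervals (0.417 to 0.469 and 0.442 to 0.486), as a mixture would give. Against 1 mixing proportion, the G2/M members lay at 0.664 (0.599 to 0.777) and the amino acid stress genes at 0.362 (0.268 to 0.433), a difference of 0.302, though genes of a group move together, so the intervals over genes may be too narrow. A mixture stays open, as does a newborn collected at a later hour, which the labels do not record and which was not tested.

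The interferon-stimulated genes rose at day 15 with a median of 2.74 (SD 1.08 over 25 genes). More macrophages alone, with unchanged expression in each, would raise their markers alike, and these had a median of 0.357 (SD 0.718 over 13 genes), with the most abundant, C1QA, at 16.2 ± 3.21 and 50.1 ± 42.6 TPM. By library, the macrophage level was highest in day 15 replicate 2 (0.89, interferon level 2.65) and day 7 replicate 5 (0.35, interferon level 1.32). It was -0.09 in day 15 replicate 6, with an interferon level of 1.77. A macrophage contribution in some libraries thus stays open. Library scaling was examined with median-of-ratios scaling, after which the median was 2.99. Its factors ran only from 0.756 (day 15 replicate 1) to 1.21 (day 0 replicate 6). A rise of this size lies beyond that range, so the outcome was fixed before the test. Age itself, housing or an infection in some animals stay open and were not tested. The level was also raised in 1 of the 3 day 7 libraries.

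CMTM5 and IL25 fell together with EFS, the next gene in the RefSeq order of Sscrofa11.1. Over the 9 libraries CMTM5 ranged 79.0-fold and IL25 79.3-fold, while their ratio ranged 1.44-fold, from 0.702 to 1.01. A fixed ratio is what reads of 1 transcript unit counted into both genes would give, so they may be a single signal. EFS ranged 12.2-fold, and within an age it varied far less than these 2 genes. In day 7 replicates 2 and 5 CMTM5 had 3.33 and 40.1 TPM, and EFS 3.13 and 3.60 TPM. In day 15 replicates 2 and 1 CMTM5 had 2.06 and 19.4 TPM, and EFS 1.74 and 2.37 TPM. The fixed ratio thus does not extend to EFS. SLC22A17, the next gene, changed by -0.90 at day 7 and -1.61 at day 15 against day 0 (limma adjusted p = 0.0129 and 8.43e-04). On the other side of CMTM5, MYH7 changed by -0.16 and -0.27. Between MYH7 and CMTM5 lie MIR208B and LOC100736765, which were not tested, so the edge of the fall on that side is not known. Shared control of neighbouring genes stays open and was not tested, and the reads that could separate these were not analysed here.

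The unnamed gene ENSSSCG00000035520 held 3576 to 4899 TPM in 7 libraries and 0.741 and 0.664 TPM in day 7 replicates 2 and 6.

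Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For day 7 against day 0, 1 of 10 splits, the real one, gave 2031 genes (highest other 2), 1 gave 643 genes at least 2-fold (highest other 2), and 4 gave 13 or more lists (highest other 17). For day 15 against day 7, 2 of 10 gave 21 or more genes (highest other 150), 2 gave 21 or more at least 2-fold (highest other 132), and 3 gave 16 or more lists (highest other 18). The split with 150 genes set day 7 replicate 5 and day 15 replicates 2 and 6 against the rest, which points to a structure of the samples beside age. The interferon-stimulated level followed this split, at 1.32, 2.65 and 1.77 in these libraries. It was -0.96 and -0.80 in day 7 replicates 2 and 6 and 0.03 in day 15 replicate 1. For day 15 against day 0, 1 of 10 gave 2933 genes and 1 gave 852 at least 2-fold (highest other 1 for each), and 8 gave 10 or more lists (highest other 14).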
